A study of Mus musculus with 36 samples.

How the data were processed

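Gene expression was measured by RNA sequencing in primary mouse prostate organoids carrying an empty vector (EV), wild-type FOXA1 (WT), FOXA1 FE255del or FOXA1 R219S in a doxycycline-inducible vector, at days 0, 1 and 11 with 3 replicates each. Per the labels, cells positive for DsRED were sorted, seeded in triplicate for each infected construct and treated with 500 ng/mL doxycycline, and libraries were made from polyadenylated RNA with a stranded kit. The labels describe DsRED as part of the induced fusion, and whether doxycycline was given before the sort is not stated in them. The labels name STAR 2.4.2a, featureCounts 1.4.3 and the mm10 genome, without their roles, and they give neither the annotation release nor the strand setting.

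The deposited tables hold, per the authors' labels and as judged from the values, expected counts per gene, 1 table of 45232 genes per library. Of the values, 298311 are not written as whole numbers, none farther than 3.0e-09 from one, and they were rounded. Of the identifiers, 44585 matched a gene symbol. Low counts are mostly even: 69.7% of values from 1 to 20 (68.2% to 71.2% in single libraries), 60.2% from 21 to 100, 54.4% from 101 to 1000 and 50.3% above that, and there are 61277 values of 2 beside 22758 of 1 and 11412 of 3. Both reads of a pair therefore appear to be counted separately. Intervals and limits from counts cover counting error only and are too narrow for that reason, and a floor counted in pairs would lie higher and the at-least folds lower.

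Library totals ran from 61476938 to 102385337 counts. Genes were kept by the filterByExpr function of edgeR 4.0.16 on the 12 groups, which left 18176. Libraries were scaled by TMM (factors 0.938 to 1.08), and 1 model with 12 group means was fitted to all 36 libraries with robust dispersion and quasi-likelihood fits (common biological coefficient of variation 0.0695, median prior degrees of freedom 8.97) in R 4.3.3. Each of 21 comparisons was tested with the quasi-likelihood F test, two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. The comparisons are each FOXA1 construct against EV on each day, each variant against WT at days 1 and 11, EV at days 1 and 11 against day 0, and the change of each construct since day 0 beside the change of EV. Levels are TMM-scaled CPM. The SE of a fold change is the absolute fitted log2 fold change without a prior count, divided by the square root of the F statistic. It is derived from the test and is no separate estimate of error, so it can be too small where 1 group has few counts. Where a compared group has no counts, the fold is a lower bound with that group set to 3 counts over its 3 libraries. Where it has 1 to 3 counts, the ratio is given with a 95% exact conditional interval.

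Sets of genes were 34 lists of pathways, cell types and lineages, fixed before the data were examined together with the comparisons, the tests, the rule for named genes and the other settings tried. A list was tested with at least 5 measured members by camera in limma 3.58.1 on log2 CPM (prior count 3), with a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over the lists of a comparison. The lists were chosen from general knowledge and not from these samples. An error that matched untested list members to unrelated genes by an old synonym was corrected after the results were seen, which removed 1 list call.

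Genes are named by a fixed rule. In the day 11 comparisons, and elsewhere where useful, these are Foxa1, Foxa2, Foxa3, Trp63, Krt5, Krt14, Krt8, Krt18, Cd24a, Pbsn, Tmprss2, Fkbp5, Chga, Syp, Vim, Cdh1 and Mki67, some of them left out of the text for brevity. Results for some other genes are not reported here. For every comparison the rule adds the 8 largest positive and 8 largest negative log2 fold changes among genes that passed, with a mean of at least 2 CPM over all libraries and all 3 libraries of 1 group above all 3 of the other. For a change since day 0 it asks that every library of the construct on that day lie on one side of every EV library. Predicted-gene names are left out. In each list described, members with the smallest p are given as examples.

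The procedure was tested on simulated data with 3 libraries per group. Of 49 genes changed 1.25-fold that were tested, 42.9% were recovered, then 54.2% of 48 at 1.5-fold, 60.9% of 46 at 2-fold and 93.9% of 49 at 4-fold. Of the 17453 genes tested there, 6 unchanged ones were called in that comparison (18 by DESeq2), none in an unchanged comparison, and none of the unchanged lists. The genes were simulated independently of one another, so the result for lists says nothing about false calls among correlated genes. Set beforehand as other settings were RLE scaling, total-count scaling, no filter on low counts, a stricter filter (1 CPM in 6 libraries and a mean of 2 CPM), only the compared groups in the fit, DESeq2 1.42.0, the replicate number as a term, an estimated correlation for lists, and each library left out in turn. After seeing the data, 2 more were added: 3 libraries that stand apart left out together, and counts halved and rounded up. No library was left out of the main results. No 2 libraries were duplicates (lowest chi-square per gene 4.02). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.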

Results

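RNA was sequenced from primary mouse prostate organoids, cultures of epithelial cells, each carrying 1 of 4 doxycycline-inducible constructs. The constructs were an empty vector (EV, called empty vehicle in the labels), wild-type FOXA1 (WT) and the FOXA1 variants FE255del and R219S. FOXA1 is a forkhead transcription factor of prostate epithelium. Each construct was sampled at days 0, 1 and 11 with 3 replicates, which gives 12 groups and 36 libraries. Doxycycline was used at 500 ng/mL, and that day 0 stands for cultures without it is known only from the names of the deposited data. Per the labels, DsRED-positive cells were sorted and seeded in triplicate for each construct, so each p-value measures the spread between cultures seeded from 1 sorted population. The libraries held 61476938 to 102385337 counts, and between 20064 and 21413 genes had a read. Mitochondrial genes took 1.32% to 4.37% of the counts. Replicates of a group correlated across genes at a Pearson r of at least 0.992, and genes are not independent replicates. Of 45232 genes, 18176 were tested. Fold changes are log2 values ± SE with n = 3 per group, levels are scaled CPM ± SD, and rose or fell is written only where the adjusted p was under 0.05. The SE comes from the test statistic and can be too small where 1 group has few counts, as for Sbp and Col14a1 against EV. Largest rises and falls are named among genes with a mean of at least 2 CPM whose compared groups did not overlap.

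Foxa1 itself, the mouse gene on the minus strand of chromosome 12 (57540628 to 57546916, mm10; ENSMUSG00000035451.6), rose after induction in each of the 3 FOXA1 constructs. At day 0 the level was 232.6 ± 5 CPM in EV, 256.5 ± 3.19 in WT, 233.2 ± 3.4 in FE255del and 228.7 ± 6.25 in R219S, and no construct passed the test against EV. At day 1 the level was 226.7 ± 4.99 CPM in EV and 414.3 ± 4.69 in WT, a rise of 0.87 ± 0.06 (adjusted p = 9.3e-15). FE255del reached 320.2 ± 27.1 CPM (0.50 ± 0.06, adjusted p = 8.5e-09) and R219S 308.6 ± 5.11 CPM (0.44 ± 0.06, adjusted p = 1.0e-07). Foxa1 was therefore lower in FE255del than in WT at day 1 (-0.37 ± 0.06, adjusted p = 3.9e-06), as it was in R219S (-0.42 ± 0.06, adjusted p = 1.6e-07). By day 11 the excess over EV was 0.22 ± 0.06 in WT (adjusted p = 0.003), 0.36 ± 0.06 in FE255del (adjusted p = 6.7e-06) and 0.22 ± 0.06 in R219S (adjusted p = 0.004). The R219S call at day 11 was lost when the 2 compared groups were fitted alone (adjusted p = 0.085) and without R219S day 11 replicate 3 (0.13, adjusted p = 0.086), with adjusted p from 3.0e-04 to 0.086 over all settings. Neither variant passed the test against WT at day 11. The species of the inserted cDNA is not given, so its reads may be counted here in part, and the Foxa1 values are no measure of the protein.

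**Figure D1:**
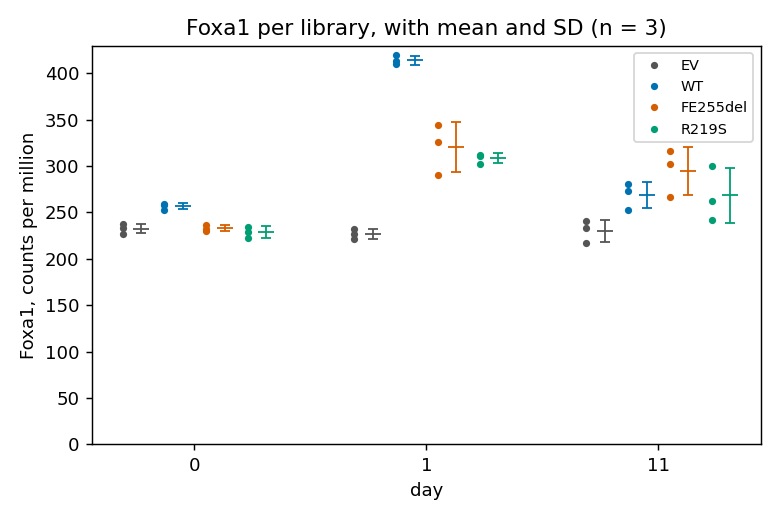
Foxa1 level in CPM (linear axis from 0) by construct and day, with 1 point per library and the mean and SD of each group. At day 1 the mean is 414.3 in WT, 320.2 in FE255del and 308.6 in R219S, beside 226.7 in EV.

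The first question is how each construct differed after 1 day from EV cultures of the same day. Differences that were there before induction are included. With WT, several secretory and receptor genes nearly silent in EV were high, while basal and squamous genes fell. Sbp, the spermine-binding protein secreted by the mouse prostate, went from 0.0198 CPM in EV to 256.7 ± 9.02 CPM (13.56 ± 0.32). Kcne2, a potassium channel subunit, reached 263.4 ± 10 CPM (12.09 ± 0.24). Several genes had no counts in EV: the B-cell lectin Cd22 was at least 5990-fold higher in WT, the goblet-cell product Retnlb at least 2890-fold and the secretin receptor Sctr at least 1130-fold. These bounds set EV at 3 counts over its 3 libraries and cover counting error only. The adhesion receptor Adgrg7 fell by 7.09 ± 0.43, and further falls were those of the BMP and Wnt antagonist Sostdc1 (-5.83 ± 0.26), the cornified envelope gene Prr9 (-5.70 ± 0.28) and the hair desmosome cadherin Dsg4 (-5.45 ± 0.28). Adgrg7 and Sostdc1 were already far below EV at day 0. Of the 25 basal epithelium genes, 1 rose and 24 fell (1 and 24 adjusted over the list alone; median -1.31, camera adjusted p = 2.8e-11, and adjusted p = 0.166 with an estimated correlation). They include the basal keratins Krt14 (-3.20 ± 0.07) and Krt5 (-1.25 ± 0.06), the basal regulator Trp63 (-1.0 ± 0.07) and the zinc-finger factor Snai2 (-2.04 ± 0.05). Squamous differentiation genes fell in 27 of 34 cases and rose in 3 (27 and 4 adjusted over the list alone; median -3.18, adjusted p = 2.2e-08, and adjusted p = 0.166 with an estimated correlation). Examples are the keratin Krt6a (-2.66 ± 0.08) and the cross-linking enzyme Tgm1 (-3.27 ± 0.12).

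Cell division genes also fell with WT at day 1. All 55 measured G2 and M phase genes fell, before and when adjusted over the list alone (median -0.96, camera adjusted p = 5.1e-19, and adjusted p = 0.244 with an estimated correlation), among them the mitotic kinase Plk1 (-1.28 ± 0.07), the spindle factor Tpx2 (-1.14 ± 0.06) and the proliferation marker Mki67 (-0.95 ± 0.08). NF-kB response genes fell in 27 of 31 cases and rose in 2 (27 and 2 adjusted over the list alone; median -1.17, adjusted p = 2.2e-09, and adjusted p = 0.166 with an estimated correlation). Among luminal and androgen-related genes the directions were mixed: the protease Tmprss2 rose (0.77 ± 0.05), while the luminal keratin Krt8 (-1.86 ± 0.07) and the androgen-responsive chaperone Fkbp5 (-1.36 ± 0.06) fell. The mesenchymal filament Vim rose (4.07 ± 0.17), while the mesenchymal transition list had a median of -0.89. Foregut and liver lineage genes rose in 11 of 18 cases and fell in 1, the same counts adjusted over the list alone (median 1.2, adjusted p = 0.005, and adjusted p = 0.166 with an estimated correlation), with the trefoil factor Tff1 at 7.68 ± 0.40. In all, 10994 of 18176 genes passed, 5382 higher and 5612 lower in WT. Scaling by total count instead moves the share of rises from 49% to 61%, and it shifts the median of all genes in this comparison by 0.12 (log2), as it does in the change of FE255del since day 0 at day 1.

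FE255del at day 1 gave a similar picture beside EV. Sbp rose to 257.5 ± 5.05 CPM (13.56 ± 0.32), its relative Sbpl by 11.37 ± 0.29, Cd22 was at least 9120-fold higher and Sctr at least 1410-fold higher. Adgrg7 fell (-8.59 ± 0.50), as did Sostdc1 (-5.79 ± 0.26) and the hyaluronan synthase Has2 (-5.29 ± 0.35). Here too Adgrg7 and Sostdc1 were already far below EV at day 0. Basal epithelium genes fell in 24 of 25 cases and rose in 1, the same counts adjusted over the list alone (median -1.32, camera adjusted p = 7.6e-15, and adjusted p = 0.196 with an estimated correlation), with Krt14 at -3.23 ± 0.07, Krt5 at -2.61 ± 0.06 and Trp63 at -1.26 ± 0.07. Squamous genes fell in 24 of 34 cases and rose in 3 (25 and 3 adjusted over the list alone; median -2.09, adjusted p = 1.4e-07, and adjusted p = 0.312 with an estimated correlation). G2 and M phase genes fell in 52 of 55 cases and none rose (53 and 0 adjusted over the list alone; median -0.53, adjusted p = 2.4e-12, and adjusted p = 0.353 with an estimated correlation). Oxidative phosphorylation genes, which encode the respiratory chain, rose in 53 of 55 cases and none fell, the same counts adjusted over the list alone (median 0.37, adjusted p = 4.6e-12, and adjusted p = 0.353 with an estimated correlation). Tmprss2 (0.97 ± 0.05) and Vim (2.32 ± 0.18) rose, and Krt8 (-1.13 ± 0.07), Fkbp5 (-1.35 ± 0.06) and Mki67 (-0.67 ± 0.08) fell. Unlike Vim, the mesenchymal transition list had a median of -1.03, and -0.17 with no low-count filter. Of 18176 genes, 9674 passed, with 4641 rises and 5033 falls. Total-count scaling moves the share of rises from 48% to 61%.

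In R219S at day 1 the largest rises were other genes, and luminal genes fell beside basal ones. Igf1, a growth factor, was at least 4810-fold higher than in EV, and the fibril-associated collagen Col14a1 went from 0.01963 to 171.4 ± 1.91 CPM (12.98 ± 0.27). The cytochrome Cyp2c29 was at least 6020-fold higher, a call lost with DESeq2 (adjusted p = 0.070, the highest of all settings, from 1.0e-12). Sbp rose to 20.46 CPM (9.91 ± 0.38). The largest falls included the urothelial plaque protein Upk3a (-4.88 ± 0.79), the phosphate transporter Slc34a2 (-3.89 ± 0.17) and the sphingomyelinase Smpd3 (-3.80 ± 0.15). Luminal epithelium genes fell in 14 of 21 cases and rose in 4 (14 and 5 adjusted over the list alone; median -0.66, camera adjusted p = 7.0e-04, and adjusted p = 0.315 with an estimated correlation), with the keratin Krt7 (-1.74 ± 0.05) and the ETS factor Elf3 (-1.34 ± 0.06) among the falls and the surface marker Cd24a (2.37 ± 0.05) among the rises. Basal epithelium genes fell in 19 of 25 cases and rose in 3, the same counts adjusted over the list alone (median -0.70, adjusted p = 2.1e-05, and adjusted p = 0.364 with an estimated correlation). Krt14 fell by 1.00 ± 0.07, while Trp63 gave 0.12 ± 0.07 (adjusted p = 0.133). Wnt response genes fell in 10 of 19 cases and rose in 3 (11 and 3 adjusted over the list alone; median -0.57, adjusted p = 0.002, and adjusted p = 0.315 with an estimated correlation), with the feedback genes Axin2 (-1.42 ± 0.05) and Tcf7 (-1.19 ± 0.06).

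The p53 response list rose in R219S at day 1: 15 of 29 members were higher and 5 lower, the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.025, and adjusted p = 0.364 with an estimated correlation). Rrm2b, a ribonucleotide reductase subunit, gave 1.56 ± 0.06, and the death receptor Fas 1.60 ± 0.08. The list was called in FE255del against EV at day 1 as well (median 0.19), though not with an estimated correlation. In the change of R219S since day 0 beside EV, no list was called higher at day 1. Ribosomal protein genes fell in 48 of 52 cases and none rose, the same counts adjusted over the list alone (median -0.31, adjusted p = 1.0e-07, and adjusted p = 0.490 with an estimated correlation). Tmprss2 fell (-0.96 ± 0.05), and Fkbp5 (0.78 ± 0.05) and Vim (4.18 ± 0.18) rose. The mesenchymal transition list had a median of -0.22. In total 8812 genes passed, 4218 higher and 4594 lower in R219S, a share of rises of 48% that becomes 56% with total-count scaling.

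Set against WT directly at day 1, FE255del had higher levels of cell division genes, and part of that gap was there at day 0. The G2 and M phase score (log2 CPM minus each gene's mean over all libraries, averaged over the members) was 0.53 ± 0.02 in FE255del and 0.29 ± 0.06 in WT at day 0. At day 1 it was -0.10 ± 0.02 and -0.48 ± 0.07. Neither variant was tested against WT at day 0, and Foxa1 was lower in FE255del than in WT at day 1. Of the 55 G2 and M phase genes, 49 were higher in FE255del than in WT and none lower (50 and 0 adjusted over the list alone; median 0.38, camera adjusted p = 5.6e-14, and adjusted p = 0.440 with an estimated correlation). Of 31 NF-kB response genes, 21 were higher and 3 lower, the same counts adjusted over the list alone (median 0.49, adjusted p = 2.8e-08, and adjusted p = 0.362 with an estimated correlation). The interleukin-33 receptor Il1rl1 was 8.82 ± 0.44 higher, the trefoil factor Tff2 6.04 ± 0.43 and the chemokine Cxcl15 4.79 ± 0.23. The club-cell secretoglobin Scgb1a1 was lower (-5.14 ± 0.23), and the cartilage collagen Col10a1 at least 3270-fold lower. Krt5 (-1.36 ± 0.06) and Vim (-1.75 ± 0.14) were lower and Krt8 (0.73 ± 0.07) higher than in WT. In all 7573 genes passed, 3956 higher and 3617 lower in FE255del, a share of 52% higher that becomes 48% with total-count scaling.

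R219S differed from WT at day 1 in 10825 genes, 5539 higher and 5286 lower, and total-count scaling moves the share of higher genes from 51% to 44%. Col14a1 was 11.28 ± 0.23 and Igf1 10.18 ± 0.32 higher in R219S, while Kcne2 was lower (-13.12 ± 0.26), and Cd22 at least 6310-fold, Siglec1 (a macrophage lectin) at least 1510-fold and Sctr at least 1190-fold lower. Basal epithelium genes were higher in 19 of 25 cases and lower in 2 (22 and 2 adjusted over the list alone; median 1.08, camera adjusted p = 2.6e-07, and adjusted p = 0.321 with an estimated correlation), with Krt14 at 2.20 ± 0.07 and Trp63 at 1.12 ± 0.07. Squamous genes were higher in 27 of 34 cases and lower in 5, the same counts adjusted over the list alone (median 2.01, adjusted p = 6.9e-06, and adjusted p = 0.321 with an estimated correlation). Fkbp5 was 2.14 ± 0.06 and Cd24a 1.65 ± 0.05 higher, and Tmprss2 lower (-1.74 ± 0.05). At day 0 the squamous score was already 0.70 ± 0.05 in R219S beside -0.20 ± 0.01 in WT, and the G2 and M phase score 0.60 ± 0.05 beside 0.29 ± 0.06. At day 1 they were 0.25 ± 0.04 beside -1.52 ± 0.05 and 0.08 ± 0.04 beside -0.48 ± 0.07. Part of both gaps was therefore there at day 0, and Foxa1 was lower in R219S than in WT at day 1. The G2 and M phase list was higher in 53 of 55 cases and lower in none (54 and 0 adjusted over the list alone; median 0.59, adjusted p = 1.4e-11, and adjusted p = 0.355 with an estimated correlation).

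The next question is which differences from EV were present after 11 days. In WT the uroplakins Upk3a and Upk1b, the secretoglobin Scgb1a1 and several genes nearly silent in EV stood far above it. Upk3a, a protein of the urothelial plaque, was at 660.6 ± 9.41 CPM beside 2.145 ± 0.79 in EV (8.25 ± 0.20), and Upk1b rose by 6.80 ± 0.13. Scgb1a1 was at 614.8 ± 104 CPM beside 5.114 ± 1.94 (6.91 ± 0.19). Tff1, a trefoil factor with 2 counts in EV, was 1210-fold higher (95% exact conditional interval 335 to 10000). Sbp, at 29.36 ± 7.15 CPM, was at least 2140-fold higher, the slow myosin chain Myh7 at least 1210-fold and Cd22 at least 366-fold. The seminal vesicle and urothelium list, whose seminal vesicle secretory genes were too low to test, rose in 3 of 8 cases with none lower, the same counts adjusted over the list alone (median 0.81, camera adjusted p = 0.011, and adjusted p = 0.137 with an estimated correlation). Lung and airway lineage genes rose in 6 of 10 cases and fell in 2, the same counts adjusted over the list alone (median 1.02, adjusted p = 0.003, and adjusted p = 0.137 with an estimated correlation), with the ciliogenesis factor Foxj1 at 2.88 ± 0.14 and the water channel Aqp5 at 1.99 ± 0.12. With no low-count filter, which adds barely expressed members, the medians of these 2 lists were 0.41 and 0.00, and that of the former was 0.52 without WT day 11 replicate 2. The lung and airway median in WT was already 0.41 at day 0, when Aqp5 was above EV as well. Basal epithelium genes fell in 19 of 25 cases and rose in 3 (20 and 3 adjusted over the list alone; median -0.43, adjusted p = 2.8e-07, and adjusted p = 0.279 with an estimated correlation), with Krt14 at -1.24 ± 0.07, Krt5 at -1.04 ± 0.05 and Trp63 at -0.26 ± 0.07.

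Interferon response genes fell in WT at day 11. Of 39, 38 were lower and 1 higher, the same counts adjusted over the list alone (median -2.0, camera adjusted p = 4.8e-24, and adjusted p = 0.137 with an estimated correlation). The nucleic acid sensor Zbp1 gave -3.74 ± 0.24 and the antiviral Oasl1 -2.85 ± 0.18, and Ifit2 was the member that rose (1.03 ± 0.07). Genes of the G2 and M phases rose in 39 of 55 cases with none lower, the same counts adjusted over the list alone (median 0.24, adjusted p = 1.3e-06, and adjusted p = 0.585 with an estimated correlation), with Mki67 at 0.42 ± 0.08. Squamous genes fell in 19 of 34 cases and rose in 3, the same counts adjusted over the list alone (median -1.08, adjusted p = 2.8e-07, and adjusted p = 0.277 with an estimated correlation). The squamous median in WT against EV was already -1.04 at day 0, and the basal epithelium median -0.29. The squamous differentiation score of WT day 11 replicate 3 was 0.328, apart from the -0.831 and -0.653 of the other 2. Krt18 (0.60 ± 0.04) and Vim (0.69 ± 0.15, and 0.45 without EV day 11 replicate 3) rose, and Fkbp5 (-1.60 ± 0.06) and Tmprss2 (-0.20 ± 0.05) fell. The mesenchymal transition list had a median of -0.54. In total 7385 genes passed, 3810 higher and 3575 lower, a share of rises of 52% that becomes 60% with total-count scaling.

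FE255del at day 11 shared the rises of Upk3a, at 934.1 ± 78.7 CPM (8.75 ± 0.21), and Upk1b (5.74 ± 0.12). The cholecystokinin receptor Cckar was at least 2110-fold higher than in EV, Sbp at least 1480-fold and Cd22 at least 425-fold. Adgrg7 (-6.94 ± 0.44), the cadherin Dsg4 (-4.78 ± 0.23) and the defensin Defb1 (-3.88 ± 0.19) fell. Foregut and liver lineage genes rose in 11 of 18 cases and fell in 1, the same counts adjusted over the list alone (median 1.88, camera adjusted p = 0.010, and adjusted p = 0.254 with an estimated correlation). Among them are Tff2 (6.79 ± 0.47), the nuclear receptor Hnf4a (3.52 ± 0.35) and the intestinal homeobox gene Cdx2 (1.66 ± 0.12). The median was 1.5 with the members silent in 1 group set to their bound and 0.71 with no low-count filter. Squamous genes fell in 24 of 34 cases and rose in 5, the same counts adjusted over the list alone (median -1.57, adjusted p = 2.5e-09, and adjusted p = 0.254 with an estimated correlation). Basal epithelium genes fell in 19 of 25 cases and rose in 3, the same counts adjusted over the list alone (median -0.43, adjusted p = 1.0e-07, and adjusted p = 0.273 with an estimated correlation), with Krt14 at -1.37 ± 0.07 and Krt5 at -1.02 ± 0.05. At day 0 the squamous median in FE255del against EV was -0.72 and the basal epithelium median -0.22. Interferon genes fell in 36 of 39 cases and rose in 1, the same counts adjusted over the list alone (median -1.15, adjusted p = 2.7e-13, and adjusted p = 0.273 with an estimated correlation). Genes of the G2 and M phases rose in 51 of 55 cases and fell in 1, the same counts adjusted over the list alone (median 0.31, adjusted p = 3.9e-09, and adjusted p = 0.395 with an estimated correlation). Fkbp5 (-1.68 ± 0.06) and Vim (-1.23 ± 0.17) fell and Tmprss2 (0.39 ± 0.05) rose. In total 7672 genes passed, 4103 higher and 3569 lower, a share of rises of 53% that becomes 58% with total-count scaling.

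In R219S at day 11 basal genes and the mesenchymal filament Vim stood above EV. Of the basal epithelium list, 17 of 25 members rose and 2 fell (18 and 2 adjusted over the list alone; median 0.28, camera adjusted p = 9.3e-05, and adjusted p = 0.836 with an estimated correlation), with the growth factor binder Igfbp3 at 3.10 ± 0.21, the laminin chain Lamb3 at 0.65 ± 0.06 and Trp63 at 0.39 ± 0.07. Krt14 rose by 0.21 ± 0.07, a call lost when the 2 groups were fitted alone (adjusted p = 0.132), without EV day 11 replicate 3 (adjusted p = 0.134) and without R219S day 11 replicate 2 (adjusted p = 0.125), with adjusted p from 0.008 to 0.134 over all settings. Vim was at 153.8 ± 8.92 CPM beside 6.197 ± 2.15 in EV (4.63 ± 0.16). The mesenchymal transition list had a median of 0.36 and was not called. Igf1, at 34.37 ± 7.98 CPM, was at least 2440-fold higher than in EV and Sbp at least 424-fold. Foxa2, a relative of Foxa1 with 2 counts in EV, both in replicate 1, was 32.1-fold higher (95% exact conditional interval 8.52 to 270). Its level in R219S was still low, with 65 counts over the group (0.3 CPM). At day 0 it already had 18 counts in R219S and none in EV. The falls included the brush border protein Vil1 (-4.48 ± 0.42), the chloride channel Cftr (-4.16 ± 0.25) and the tetraspanin Tspan8 (-3.66 ± 0.13). G2 and M phase genes fell in 29 of 55 cases and rose in 1 (35 and 1 adjusted over the list alone; median -0.20, adjusted p = 1.7e-06, and adjusted p = 0.836 with an estimated correlation), with a median of -0.13 without R219S day 11 replicate 1. Interferon genes rose in 4 and fell in 6 of 39 cases (median -0.14, adjusted p = 0.175). Krt8 (-0.89 ± 0.07) and Tmprss2 (-0.73 ± 0.05) fell. The epithelial cadherin Cdh1 was above EV at day 11 in WT (0.33 ± 0.04), FE255del (0.32 ± 0.04) and R219S (0.29 ± 0.04), as was Cd24a (0.18 ± 0.05, 0.39 ± 0.05 and 0.89 ± 0.05). Of 5833 genes that passed in R219S, 3220 were higher and 2613 lower. Total-count scaling moves the share of rises from 55% to 43%, and fitting the 2 groups alone gives 3817 genes.

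**Figure D2:**
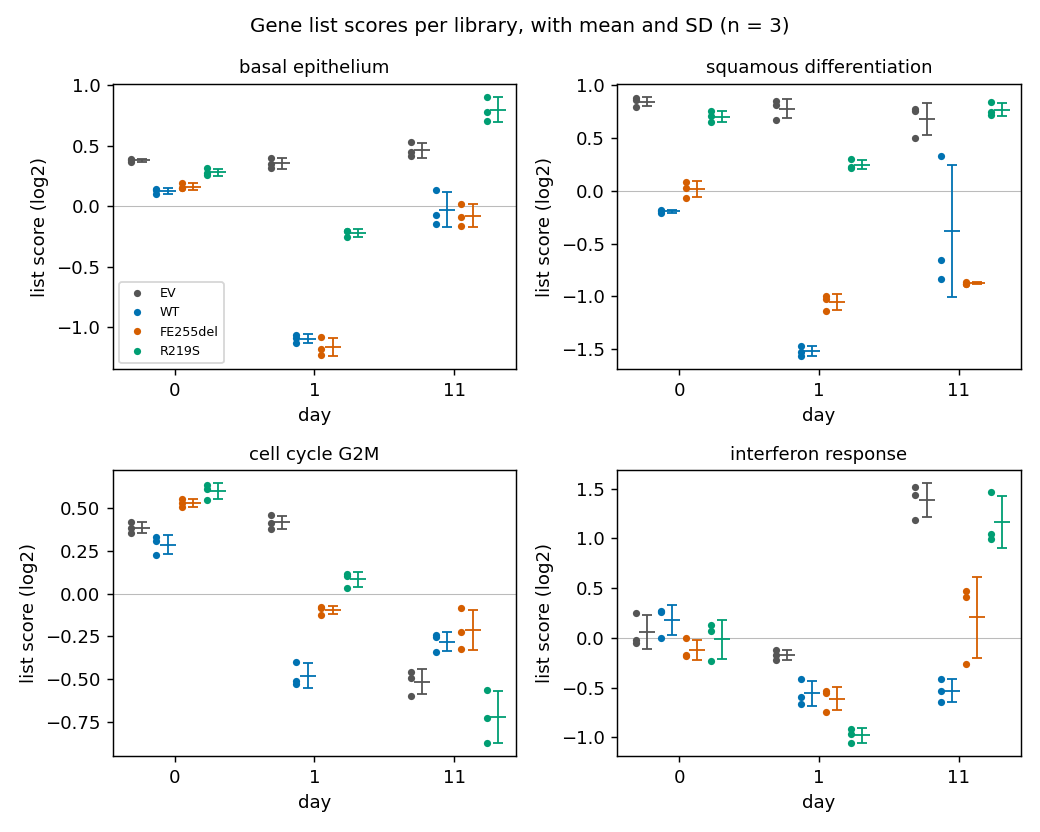
List scores (log2, the mean over the members of their log2 CPM minus each gene's mean over all libraries) by day for basal epithelium, squamous differentiation, G2 and M phase and interferon response, with 1 point per library and the group mean and SD. The basal epithelium score at day 1 is 0.36 ± 0.04 in EV, -1.09 ± 0.03 in WT, -1.16 ± 0.08 in FE255del and -0.22 ± 0.03 in R219S, and the interferon response score at day 11 is 1.38 ± 0.17, -0.53 ± 0.12, 0.21 ± 0.41 and 1.17 ± 0.26.

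Between the FOXA1 constructs at day 11, FE255del was closer to WT than R219S was. In FE255del against WT, 3213 genes passed, 1773 higher and 1440 lower, and 1706 passed when the 2 groups were fitted alone. The share of higher genes was 55%, and 47% with total-count scaling. Scgb1a1 was at 0.9634 CPM in FE255del beside 614.8 in WT (-9.32 ± 0.22), and the secreted mucosal proteins Retnlb (-6.30 ± 0.37) and Tff1 (-5.78 ± 0.34) were lower too. Tff2 (6.20 ± 0.44), the vanin Vnn3 (4.84 ± 0.17) and the protease inhibitor Spink5 (4.10 ± 0.14) were higher. Interferon genes were higher in FE255del in 31 of 39 cases and lower in none (34 and 0 adjusted over the list alone; median 0.77, camera adjusted p = 1.1e-13, and adjusted p = 0.688 with an estimated correlation). Vim (-1.93 ± 0.17) was lower and Tmprss2 (0.58 ± 0.05) higher, while Krt5 gave 0.02 ± 0.05 and Krt14 -0.13 ± 0.07, neither past the test. In R219S against WT, 8883 genes passed, 4500 higher and 4383 lower, a share of rises that total-count scaling moves from 51% to 37%. Upk3a (-11.62 ± 0.26) and Scgb1a1 (-10.24 ± 0.24) were lower in R219S, and Col14a1 (9.34 ± 0.22) and Igf1 (9.53 ± 0.34) higher. Basal epithelium genes were higher in 21 of 25 cases and lower in 2, the same counts adjusted over the list alone (median 0.76, adjusted p = 6.9e-10, and adjusted p = 0.279 with an estimated correlation), with Krt14 at 1.45 ± 0.07 and Krt5 at 1.15 ± 0.06. G2 and M phase genes were lower in 49 of 55 cases and higher in 1, the same counts adjusted over the list alone (median -0.46, adjusted p = 9.6e-13, and adjusted p = 0.380 with an estimated correlation).

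Across genes, the day 11 changes from EV correlated at 0.81 between WT and FE255del, 0.21 between WT and R219S and 0.17 between FE255del and R219S. All 3 pairs share the EV libraries, and simulated data in which nothing but that control was shared gave 0.50. Both R219S correlations were below that, but the simulated groups held no change of their own, so 0.50 is no reference for these correlations. On the covariance scale, by contrast, the values were 0.530, 0.118 and 0.104 beside 0.0262 simulated. In WT and FE255del 2859 genes rose in both and 2704 fell in both, where independence would give 860 and 702, and 116 went opposite ways. In WT and R219S 1042 rose in both and 917 fell in both, where independence would give 675 and 514, and 1537 went opposite ways. In FE255del and R219S 994 rose in both and 915 fell in both, where independence would give 727 and 513, and 1677 went opposite ways. Independence leaves out the shared EV libraries, so part of any excess may come from them. No such value was computed for the opposite counts, which exceed either shared count in both R219S pairs. The shared counts alone therefore do not show that R219S moved genes the same way as the other constructs. In 20 simulations of unchanged groups that share the EV libraries, at most 1 gene rose in both and none fell in both, but at most 4 genes were called in any such group, so this is no reference for the observed overlaps.

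**Figure D3:**
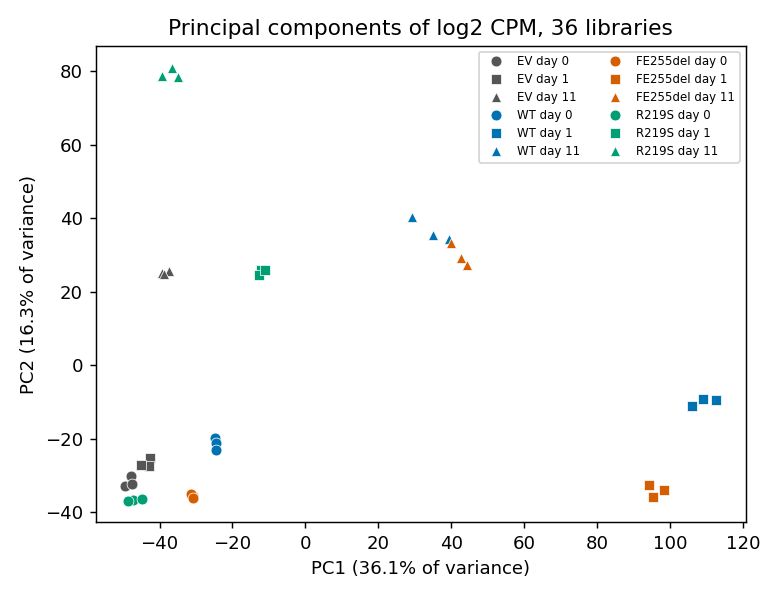
First and second principal components of log2 CPM (36.1% and 16.3% of variance) with 1 point per library, coloured by construct and shaped by day. On the first component the WT day 1 libraries lie at 105.9 to 112.6 and the FE255del day 1 libraries at 94.2 to 98.3, while the R219S day 1 libraries lie at -12.7 to -11 and the EV day 1 libraries at -45.2 to -42.7.

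At day 0 the constructs already differed from EV. In WT the ETS factor Spdef (4.37 ± 0.33) and the phospholipase Plcb4 (3.58 ± 0.19) rose, and the hyaluronan-binding chain Itih2, with 2 counts in EV, was 94.6-fold higher (95% exact conditional interval 25.8 to 786). Sostdc1 (-5.27 ± 0.25) and Adgrg7 (-4.76 ± 0.35) were already lower than in EV, so much of their gap at day 1 was there before induction. Squamous genes fell in 24 of 34 cases and rose in 1 (25 and 2 adjusted over the list alone; median -1.04, camera adjusted p = 9.3e-14, and adjusted p = 0.084 with an estimated correlation). Lung and airway lineage genes rose in 5 of 10 cases with none lower (6 and 0 adjusted over the list alone; median 0.41, adjusted p = 7.2e-05, and adjusted p = 0.014 with an estimated correlation), with Aqp5 at 2.63 ± 0.13 and the surfactant protein Sftpd at 1.52 ± 0.12. The median of this list was 0.22 with no low-count filter and 0.62 with counts halved. In all 4132 genes passed in WT, 1799 higher and 2333 lower, with 44% rises that become 52% with total-count scaling.

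FE255del at day 0 had higher Wnt5a, a secreted Wnt ligand (2.97 ± 0.18), and lower Adgrg7 (-4.88 ± 0.36), Sostdc1 (-4.67 ± 0.24) and the surface antigen Ly6d (-2.62 ± 0.22) than EV. Squamous genes fell in 24 of 34 cases with none higher (27 and 0 adjusted over the list alone; median -0.72, camera adjusted p = 8.2e-13, and adjusted p = 0.217 with an estimated correlation). Myc targets, genes of ribosome production, rose in 25 of 32 cases with none lower (28 and 0 adjusted over the list alone; median 0.18, adjusted p = 5.0e-12, and adjusted p = 0.277 with an estimated correlation). Of 3776 genes that passed, 2010 were higher and 1766 lower, with 53% rises that become 47% with total-count scaling. R219S at day 0 showed smaller changes, led by falls of Sostdc1 (-2.49 ± 0.19) and Adgrg7 (-2.48 ± 0.29) and a rise of the fatty acid oxidation enzyme Decr1 (1.66 ± 0.09). There Myc targets rose in 28 of 32 cases with none lower (32 and 0 adjusted over the list alone; median 0.28, adjusted p = 5.5e-22, and adjusted p = 0.043 with an estimated correlation), including Mybbp1a (0.40 ± 0.04) and the RNA helicase Ddx21 (0.32 ± 0.04). G2 and M phase genes rose in 40 of 55 cases with none lower (45 and 0 adjusted over the list alone; median 0.22, adjusted p = 1.6e-12, and adjusted p = 0.459 with an estimated correlation). The seminal vesicle and urothelium list fell in 3 of 8 cases with none higher (4 and 0 adjusted over the list alone; median -0.61, adjusted p = 0.002, and adjusted p = 0.043 with an estimated correlation), with a median of -0.98 without R219S day 0 replicate 1. In R219S 3654 genes passed, 2397 higher and 1257 lower, and total-count scaling moves the share of rises from 66% to 47%. R219S day 0 replicate 2 had the largest total, 102385337 counts, and the lowest mitochondrial share, 1.32%, and with the 3 libraries that stand apart left out 1246 genes rose and 1256 fell. Without EV day 0 replicate 2 the counts were 2490 in FE255del and 2091 in R219S.

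EV cultures were followed over time to see what changed without a FOXA1 insert. From day 0 to day 1 few genes changed: 260 passed, 47 higher and 213 lower. Glycolysis and hypoxia genes fell in 12 of 30 cases with none higher (27 lower and 1 higher adjusted over the list alone; median -0.22, camera adjusted p = 1.3e-24, and adjusted p = 0.038 with an estimated correlation), with the glycolytic regulator Pfkfb3 at -0.37 ± 0.06 and the glucose transporter Slc2a1 at -0.29 ± 0.06. Immediate early genes fell in 5 of 24 cases with none higher (11 and 0 adjusted over the list alone; median -0.14, adjusted p = 1.3e-08, and adjusted p = 0.038 with an estimated correlation), with the stress factor Atf3 at -0.67 ± 0.11. Nitric oxide synthase Nos2 fell (-0.88 ± 0.15). The gene count depends on single libraries: it was 87 without EV day 0 replicate 1, 104 without EV day 0 replicate 2, 94 without EV day 1 replicate 1, 62 without EV day 1 replicate 2 and 123 without EV day 1 replicate 3. It was 658 with the 2 groups fitted alone, 396 with DESeq2 and 171 with a stricter filter.

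From day 0 to day 11 EV changed in 8657 genes, 4191 higher and 4466 lower, with 48% rises that become 53% with total-count scaling. Interferon response genes rose in 38 of 39 cases with none lower, the same counts adjusted over the list alone (median 1.19, camera adjusted p = 1.7e-16, and adjusted p = 0.188 with an estimated correlation), among them Ifit1 (2.20 ± 0.20) and the immunoproteasome subunit Psmb8 (1.95 ± 0.18). Ifi27l2a, interferon-induced as well, went from 3.411 ± 1.12 to 71.1 ± 18.9 CPM (4.39 ± 0.39). Genes of the G2 and M phases fell in 54 of 55 cases with none higher, the same counts adjusted over the list alone (median -0.97, adjusted p = 5.9e-35, and adjusted p = 0.173 with an estimated correlation), with Mki67 at -1.08 ± 0.08. Cholesterol synthesis genes fell in 25 of 25 cases, the same count adjusted over the list alone (median -0.71, adjusted p = 1.3e-17, and adjusted p = 0.173 with an estimated correlation), with Idi1 at -1.29 ± 0.08 and Cyp51 at -1.0 ± 0.05. The neutrophil chemokines Cxcl3 (-5.30 ± 0.17), Ppbp (-3.95 ± 0.29) and Cxcl1 (-2.60 ± 0.09) were among the largest falls. Krt5 (0.40 ± 0.05) and Trp63 (0.50 ± 0.07) rose, and Krt8 (-0.53 ± 0.07), Krt18 (-0.60 ± 0.04) and Fkbp5 (-0.76 ± 0.05) fell.

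To separate induced changes from those present at day 0, the change of each construct since day 0 was compared with that of EV. At day 1, 7992 genes changed differently in WT (3669 higher, 4323 lower), 7314 in FE255del (3155 and 4159) and 7153 in R219S (2924 and 4229). Total-count scaling moves the shares of rises from 46% to 58%, 43% to 59% and 41% to 55%. Foxa1 gave 0.73 ± 0.08 in WT, 0.49 ± 0.08 in FE255del and 0.47 ± 0.08 in R219S. Basal epithelium genes fell in 21 of 25 cases in WT and rose in 1 (21 and 2 adjusted over the list alone; median -1.20, camera adjusted p = 2.3e-11, and adjusted p = 0.228 with an estimated correlation). In FE255del 23 fell and 1 rose, the same counts adjusted over the list alone (median -1.23, adjusted p = 4.0e-15, and adjusted p = 0.198 with an estimated correlation). G2 and M phase genes fell in 55, 54 and 52 of 55 cases in WT, FE255del and R219S, with none higher (55, 54 and 53 adjusted over the list alone; medians -0.86, -0.67 and -0.58). The adjusted p of these 3 tests was 1.5e-19, 5.5e-17 and 6.6e-14, and with an estimated correlation 0.242, 0.322 and 0.366. In R219S all 52 ribosomal protein genes fell, before and when adjusted over the list alone (median -0.39, adjusted p = 8.7e-10, and adjusted p = 0.495 with an estimated correlation). Col14a1 gave 11.85 ± 1.46 in R219S. The large falls included Ankrd1, a cardiac and YAP-responsive gene (-3.66 ± 0.30), in WT, the sugar-digesting enzyme Mgam (-4.27 ± 0.31) in FE255del and Smpd3 (-3.47 ± 0.19) in R219S.

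At day 11 the same test passed 3897 genes in WT (1982 higher, 1915 lower), 3729 in FE255del (1716 and 2013) and 4931 in R219S (2252 and 2679). The shares of rises were 51%, 46% and 46%, and 56%, 55% and 44% with total-count scaling. Interferon response genes in WT fell in 38 of 39 cases with none higher (38 and 1 adjusted over the list alone; median -2.10, camera adjusted p = 2.4e-36, and adjusted p = 0.063 with an estimated correlation), including the antiviral Oas3 (-4.22 ± 0.44) and Ifi44 (-3.94 ± 0.45). In FE255del 28 fell and 1 rose (31 and 2 adjusted over the list alone; median -0.80, adjusted p = 6.9e-12, and adjusted p = 0.477 with an estimated correlation). The seminal vesicle and urothelium list rose in 3 of 8 cases in WT with none lower (4 and 0 adjusted over the list alone; median 1.07, adjusted p = 7.3e-04, and adjusted p = 0.028 with an estimated correlation). In FE255del it rose in 4 with none lower, the same counts adjusted over the list alone (median 0.84, adjusted p = 1.7e-04, and adjusted p = 0.009 with an estimated correlation), with a median of 0.35 under no low-count filter. In R219S basal epithelium genes rose in 18 of 25 cases with none lower (19 and 1 adjusted over the list alone; median 0.38, adjusted p = 3.6e-08, and adjusted p = 0.453 with an estimated correlation). Myc targets fell there in 29 of 32 cases with none higher (31 and 0 adjusted over the list alone; median -0.33, adjusted p = 8.5e-13, and adjusted p = 0.453 with an estimated correlation). Mesenchymal transition genes rose in R219S in 12 of 29 cases and fell in 2 (14 and 2 adjusted over the list alone; median 0.54, adjusted p = 5.8e-04, and adjusted p = 0.453 with an estimated correlation). Part of this comes from day 0, when the median of this list in R219S against EV was -0.29. In R219S against EV at day 11 the list was not called (median 0.36). The mitochondrially encoded list rose in R219S in 4 of 10 cases with none lower (7 and 0 adjusted over the list alone; median 0.67, adjusted p = 0.014, and adjusted p = 0.767 with an estimated correlation). That call was lost without R219S day 0 replicate 2 (median 0.44, adjusted p = 0.124) and without R219S day 11 replicate 2, the library with the highest mitochondrial share (median 0.39, adjusted p = 0.096). With the 3 libraries that stand apart left out together it was lost as well (median 0.16, adjusted p = 0.456). Its median was 1.01 without R219S day 0 replicate 3, and the adjusted p ran from 3.3e-04 to 0.456 over all settings with the preset correlation. Col14a1 gave 7.52 ± 1.18 and Tspan8 -3.09 ± 0.16 in R219S.

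Of 714 list tests over the 21 comparisons, 288 were called with the preset correlation and 7 of those calls held with an estimated correlation. These 7 are the lung and airway lineage in WT at day 0, the Myc targets and the seminal vesicle and urothelium list in R219S at day 0, glycolysis and hypoxia and immediate early genes in EV at day 1, and the seminal vesicle and urothelium list in the day 11 changes of WT and FE255del. The Notch list differed in sign between its summaries at day 1: the median was -0.53 in WT and -0.54 in FE255del, the mean 0.40, and the test called it lower (adjusted p = 0.023 and 0.025, and adjusted p = 0.244 and 0.346 with an estimated correlation). In WT at day 11 the Wnt response list had a median of -0.25 and a mean of 0.31 and was called lower (adjusted p = 0.013, and adjusted p = 0.306 with an estimated correlation).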

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

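The tests of a difference between days 1 and 11 are not among the 21 comparisons set beforehand. Which genes and lists had opposite directions was known only after the results were seen, and no explanation was tested for them. Each value below is the effect of a construct against EV at day 11 minus that at day 1 (log2), where both effects passed their tests with opposite signs and the difference passed its own. For a list it is the median of the differences of its members, which is not the difference of the 2 medians.

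In WT, Krt18 was below EV at day 1 (-0.68) and above it at day 11 (0.60), a difference of 1.28, and Mki67 likewise (-0.95, then 0.42), a difference of 1.37. Tmprss2 was above EV at day 1 (0.77) and below it at day 11 (-0.20), a difference of -0.97. The S phase list (median -0.65, then 0.29) differed by 0.97, the G2 and M phase list (-0.96, then 0.24) by 1.22 and the Myc targets (-0.40, then 0.12) by 0.52. In FE255del, Krt18 differed by 0.58, Mki67 by 1.08 and Vim by -3.55 (2.32 at day 1, -1.23 at day 11). The S phase list differed by 0.61 there, G2 and M phase by 0.86 and cholesterol synthesis by 0.55. In R219S, Krt14 differed by 1.21, Fkbp5 by -1.08, Cdh1 by 0.42 and the basal epithelium list by 0.93 (-0.70, then 0.28). The list differences were all lost with an estimated correlation (adjusted p from 0.10 for basal epithelium in R219S to 0.362 for cholesterol synthesis in FE255del).

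Over all tested genes, the 2 days gave called effects of opposite sign for 1304 genes in WT, 839 of them lower and then higher. The number was 935 in FE255del, 620 of them lower and then higher, and 609 in R219S, 431 of them lower and then higher. The day 11 effects on cell division are relative to EV cultures in which the same genes had fallen since day 0 (a list call lost with an estimated correlation, adjusted p = 0.173), with a G2 and M phase score of 0.42 ± 0.04 at day 1 and -0.52 ± 0.07 at day 11 (SD, n = 3).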

How the results depend on the processing

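No named gene or list result called in the main run or in the alternative turned its sign in the alternatives run for it. Lists were not tested under RLE scaling, DESeq2, the stricter filter or with the compared groups fitted alone. Leaving out the 3 libraries that stand apart and halving the counts were chosen only after the results were seen. With the compared groups fitted alone, 3817 genes passed for R219S against EV at day 11 (5833 with all groups), 1706 for FE255del against WT at day 11 (3213) and 658 for EV at day 1 against day 0 (260). The last count was 396 with DESeq2 and 171 with the stricter filter, which tests fewer genes. The cause was not tested for the others. With an estimated correlation 7 gene lists were called in place of 288. With 1 library left out, the count for FE255del against EV at day 0 ran from 2490 to 3486 (3776 with all), for R219S against EV at day 0 from 2091 to 3512 (3654), and for EV at day 1 against day 0 from 62 to 180 (260). With 1 EV day 11 library left out, the only ones tried there, the correlation of day 11 effects between FE255del and R219S ran from 0.18 to 0.22 (0.17), the highest without EV day 11 replicate 1. Fits without a library have fewer samples, and the cause of each move was not tested.

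The other counts stayed within 1.5 times: WT against EV at day 1 ran from 8666 to 11289 over the settings (10994 in the report), and WT against EV at day 11 from 6007 to 7788 (7385). With counts halved all 22 counts did, and of the list calls 7 were gained and 7 lost. Of the named gene results, 1731 kept their call with counts halved, 1 was gained and 10 were lost. DESeq2 kept 1719, gained 4 and lost 13, total-count scaling kept 1722, gained 9 and lost 11, RLE scaling kept 1733, gained 2 and lost 7, and no filter kept 1712 and lost 30. Leaving out the 3 libraries that stand apart kept 592, gained 2 and lost 26. Over all single libraries left out, 13152 comparisons of a named gene kept the call, 14 were gained and 334 lost. For lists these were 5321, 116 and 71. Of the 16 day differences, 13 moved by at least a set limit under total-count scaling, with the same sign. The limit was the SE from the test for a gene, and the SD of library scores within groups for a list.

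Replicate numbers pair samples of different groups in no consistent way: of the pairs of groups compared, R219S day 0 with WT day 1 alone had each same-number correlation above 0.1 (0.21, 0.34 and 0.16). With the replicate block as a term, 1731 named gene results kept their call, 5 were gained and 6 lost, and 287 lists were called. Depth limits folds of genes with few counts in EV, which are bounds. Setting genes with no counts in 1 group to their bound moved 17 of 510 list medians by over 0.05, the largest by 0.83.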

Other observations

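The tests of direction at day 0 were written before their results were seen. All other tests of explanations below, the other splits of the libraries among them, were chosen or written after.

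The androgen response list, where a FOXA1 effect might be looked for first, was not called in any construct against EV at day 1 or day 11, although many members moved. At day 1, 18 of its 54 members rose and 30 fell in WT (median -0.21, adjusted p = 0.078), 17 rose and 26 fell in FE255del (median -0.20, adjusted p = 0.083), and 16 rose and 26 fell in R219S (median -0.13, adjusted p = 0.189). The means were -0.00, 0.08 and 0.07, so those of the variants differ in sign from the medians. At day 11 the medians were 0.02, -0.02 and 0.08.

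Targets of YAP and TEAD, the effectors of Hippo signalling, fell at day 1 in 18 of 25 cases in WT and rose in 5 (median -0.74, camera adjusted p = 0.002, and adjusted p = 0.244 with an estimated correlation). In FE255del 16 fell and 6 rose (median -0.58, adjusted p = 0.007, and adjusted p = 0.353 with an estimated correlation), and in R219S 15 fell and 6 rose (median -0.25, adjusted p = 0.026, and adjusted p = 0.435 with an estimated correlation). The counts adjusted over the list alone were the same. At day 11 none of the 3 passed. Tight and adherens junction genes fell at day 1 in R219S in 22 of 29 cases and rose in 3 (23 and 4 adjusted over the list alone; median -0.32, adjusted p = 2.1e-05, and adjusted p = 0.315 with an estimated correlation).

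Some markers of other cell types were expressed while others were nearly absent. The macrophage receptor Csf1r reached 67.7 CPM in WT at day 1 and the lysosomal marker Cd68 7.37 CPM in FE255del at day 11, and the general leukocyte gene Ptprc averaged 0.0488 CPM over all libraries. Among stromal genes, Dcn reached 37.5 CPM in R219S, Fbln1 17.8 CPM in EV and Acta2 29 CPM in WT, all at day 11, and the fibroblast collagen Col1a2 averaged 0.0014 CPM. Of the endothelial genes, Pecam1 reached 6.78 CPM and Flt1 14.7 CPM in FE255del at day 1, and Cdh5 averaged 0.00241 CPM. None of the immune, stromal and endothelial lists was called against EV at day 1 or day 11.

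All 3 constructs differed from EV at day 0, and a candidate explanation is expression of the construct before doxycycline. It predicted that over 60% of the genes called at day 0 would move further the same way by day 1, and at most 50% otherwise. The share was 45.4% in FE255del (44.2% to 47.7% in separate libraries) and 33.8% in R219S (32.5% to 36.8%), both under the lower bound. These shares cannot decide the question, since expression before doxycycline could last longer than 1 day and effects changed with time. Called effects had opposite signs on the 2 later days for 935 genes in FE255del and 609 in R219S. The G2 and M phase median in FE255del was 0.14 at day 0, -0.53 at day 1 and 0.31 on the last day. In R219S it was 0.22, -0.36 and -0.20. Without the deepest library, R219S day 0 replicate 2, 2547 genes still passed in R219S. In WT the share was 59.1%, between the 2 bounds, so construct expression cannot be told apart from other causes there either. Among genes called in both tests the share was 62.4% in WT, 47.8% in FE255del and 31.7% in R219S. Some genes had no count in EV at days 0 and 1 and were called higher in a construct at day 1, with at least 100 counts. In WT 73 such genes held 174 counts at day 0 (in 22 of them) and 84728 at day 1. In FE255del 71 held 59 and 80578, and in R219S 41 held 22 and 54407. The median day 0 level was 0% of day 1 in each, and the highest 33.2%, 3.65% and 3.64%. For these genes this argues against expression near the induced level, and a smaller part stays open. Sostdc1 and Adgrg7 fell at day 0 in all 3 constructs. An earlier pulse during the DsRED sort, and chance differences between the sorted populations, stay open as untested.

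Interferon genes were lower in WT than in EV at day 11, by a median of -2.0, a list call lost with an estimated correlation (adjusted p = 0.137). A single unusual library would bring the median near 0 when left out, and the highest median without 1 library was -1.76 (without EV day 11 replicate 3). Immune cells in the EV cultures would bring their abundant transcripts, and the highest mean among Ptprc, Tyrobp, Lyz2, C1qa and Cd3e in EV at day 11 was 0.0282 CPM. An effect of the construct may therefore be involved, since the score was 1.38 ± 0.17 in EV, 1.17 ± 0.26 in R219S, 0.21 ± 0.41 in FE255del and -0.53 ± 0.12 in WT. What raised the genes in EV after day 0 (a list call also lost with an estimated correlation, adjusted p = 0.188) was not measured, and a difference between the sorted populations stays open.

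Igf1, Col14a1 and Dcn, genes of connective tissue, were higher in R219S than in EV at day 11. Fibroblasts among the cells would bring their abundant collagens, and the higher of Col1a2 and Col3a1 reached 0.76% of the level of Dcn. This argues against fibroblasts as the source, and expression of these genes by the organoid cells may be the simpler reading. It was not tested at the level of single cells, and the DsRED sort would also remove cells without the construct.

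The gene counts were also computed for other splits of the same libraries, fitted alone. For each of the 15 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Against EV the real counts were 5385, 4945 and 3659 at day 0 for WT, FE255del and R219S, 10463, 10067 and 9624 at day 1, and 6007, 5836 and 3817 at day 11. Against WT they were 7495 and 10620 at day 1 and 1706 and 7079 at day 11 for FE255del and R219S, and in EV 658 and 8150 at days 1 and 11 against day 0. The highest other split gave 411 for FE255del against WT at day 11 and 0 elsewhere.

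For the changes since day 0 beside EV, 40 splits, the real one included, were drawn. As many genes came from 1 of 40, the real one, for R219S at day 1 (7503 genes, 6400 in the highest other), WT at day 11 (3697, 3510) and R219S at day 11 (3756, 2144). They came from 2 of 40 for WT at day 1 (8287, 10262 in the other), FE255del at day 1 (8093, 9437) and FE255del at day 11 (3280, 3982). In all 6 the highest other split kept the later-day groups apart and regrouped or exchanged only the day 0 libraries, so it still held the difference between the constructs on the later day. Whether chance is excluded for these changes therefore stays open. Splits that mixed the later-day groups gave at most 42, 36 and 1 genes at day 1 and 59, 241 and 418 at day 11 for WT, FE255del and R219S.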
